A study of Oryctolagus cuniculus with 6 samples.

How the data were processed

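Newly formed tissue from defects in the skull of male New Zealand White rabbits (Oryctolagus cuniculus) was measured on 6 single-dye arrays, 1 for each of 2 treatments on days 3, 5 and 7. Per the labels' protocols, 24 rabbits received circular parietal defects 5 mm wide, of which those on the right were filled with 0.2 g of HPD, called human particulated dentin in the series title, while the others stayed empty as controls. The labels do not say whether RNA of several animals was pooled for an array, so each array is treated as 1 sample (n = 1 per treatment and day). The series' design text mentions blood samples besides bone tissue, but the labels describe all 6 samples as newly formed tissue.

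Per the labels' protocols, RNA was column-purified with DNase digestion, checked for quality, amplified from 0.2 μg and labelled with Cy3. The deposited values are spot intensity values on a linear scale. Per the file headers, they came from Agilent Feature Extraction on a rabbit array designed against oryCun2, with spatial detrending, background subtraction, multiplicative detrending and substitute values for dim spots switched on, and no step between arrays is recorded. Each array held 45220 spots, of which 43803 were not control spots, for 43603 probes. Between 78.1% and 86.4% of these spots were well above background (84.2%, 86.4%, 84.4%, 81.5%, 85.3% and 78.1% for control and HPD of day 3, day 5 and day 7 in turn), substitute values stood in for 4.59% to 8.80%, and 0 spots were saturated. The 75th percentile of the intensity ran from 309 (control, day 7) to 471 (control, day 3). For arrays, their number and not a read depth limits the precision.

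The main values were log2 of the processed intensity minus each array's 75th percentile over non-control probes. Spots with an outlier mark were left out, which removed 41 probes, and repeated spots of a probe were averaged. Probes were named through the array's own columns and a RefSeq gene table of assembly mOryCun1.1, used for names only because its build differs. A symbol was found for 22987 probes; 20616 stayed without a single symbol, 21 of them because several fitted. For a gene with several probes the brightest was used (4465 of the 9333 named genes tested). Unnamed probes were kept under the array's own gene identifier, again with the brightest where several probes shared it. Features well above background on at least 3 of the 6 arrays were tested, which left 20089 of 23222. Coordinates are those in the files, on oryCun2.

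The fit was made with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8), with day and treatment as additive terms over all 6 arrays and Benjamini-Hochberg adjustment at 0.05. Control and HPD defects lay in the same animals, and it was assumed that both arrays of a day came from the same ones. Day therefore acts as the block, and the residual (2 degrees of freedom, 2.47 from the prior) holds both array noise and any variation of the HPD effect between days. Such p-values measure only the spread between these arrays. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. On a single day the arrays were compared without a test, by the count of features at least 2-fold apart among those well above background on both arrays. Where only 1 array of a day was well above background, the brighter value against the higher of the dim probe's own value and the lowest signal well above background gives an "at least" fold.

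In all, 25 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. They are osteoblast and bone matrix, osteoclast, cartilage, TGF-beta and BMP signalling, Wnt signalling, granulation tissue matrix, matrix proteases and inhibitors, inflammatory cytokines and chemokines, neutrophil, macrophage and monocyte, lymphocyte, mast cell, endothelial, angiogenic factors, cell cycle, hypoxia and glycolysis, interferon response, unfolded protein response and stress, skeletal muscle, erythroid and blood, brain and meninges, adipocyte, epidermis, tooth formation and reference genes. For a single day, a list's median is given with its percentile among 10000 random lists of the same size matched on mean expression, as a description of those arrays. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule takes the 10 highest and 10 lowest genes for the HPD effect and for day 7 minus day 3, the 5 highest and 5 lowest on each day, up to 4 members of each list per comparison and a fixed set of bone, inflammation and growth factor genes, of which ALPL, BGLAP and VEGFA were not named on the array. Where too few genes passed the test, the places were filled with genes well above background on all 6 arrays and moving the same way throughout, given as values only. For day 7 minus day 3 these were ranked by size. For the HPD effect they were ranked by the smallest of their 3 absolute differences, so genes with a larger mean could be left out. That ranking favours genes alike on all days and thus small SEs.

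The fit was tested on simulated data for the HPD effect over 20089 features with the spread of these arrays. It called 0 of 62 features changed 2-fold, 43 of 58 changed 4-fold and 71 of 80 changed 8-fold, all with the right sign, and 5 of 19889 unchanged ones. The 2 arrays of day 3 shared a slide and the other 4 arrays another, so the HPD comparison lies within slides, while day 3 against later days also compares slides. Alternatives were quantile normalization, a shift by the median of well-above-background probes, normexp (offset 50) on the raw and local background intensity, the mean of a gene's probes, other filters on dim features, an intensity trend with a robust prior, a fit without the day block, leaving out each day, camera with an estimated correlation, fry, and other fold thresholds. Slide in place of day as the block, and leaving out a day for the day comparisons, were added after seeing the data.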

Results

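Healing tissue of rabbit skull defects was profiled 3, 5 and 7 days after surgery, with and without HPD, ground human dentin used as a graft, on 1 array per treatment and day. All values are log2 signal scaled to the array's 75th percentile, differences are HPD minus control or the later minus the earlier day, and a standard error (SE) comes from the limma fit over all 6 arrays. Across features the arrays correlated at 0.938 to 0.984. The first principal component, 52.0% of the variance, placed control and HPD of day 3 at -75.4 and -47.6, those of day 5 at 36.5 and -1.96, and those of day 7 at 45.6 and 42.9. There was no replicate within a treatment and day.

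The comparison of filled with empty defects asked what the graft altered in the healing tissue across the 3 days. LPL, which encodes lipoprotein lipase (NM_001177330, chromosome 15, 4570223 to 4574051), was 2.76-fold, 2.74-fold and 2.85-fold higher with HPD on days 3, 5 and 7, a mean difference of 1.48 ± 0.13 (SE, 6 arrays). EGLN3, a hypoxia-induced prolyl hydroxylase (ENSOCUT00000008555, chromosome 17, 53707157 to 53708040), was 5.94-fold, 14.2-fold and 2.66-fold higher, with a mean of 2.60 ± 0.48. The macrophage elastase gene MMP12 (NM_001082771, chromosome 1, 113701478 to 113701537) had a mean of 1.65 ± 0.24, and KMO, an enzyme of tryptophan breakdown, one of 1.57 ± 0.18. The galectin genes LGALS3 and LGALS4 stood at 1.23 ± 0.14 and 1.32 ± 0.14, the chemokine gene CXCL5 at 1.53 ± 0.32, the interleukin-1 antagonist gene IL1RN at 1.54 ± 0.24, the prostaglandin synthase gene PTGS2 at 1.37 ± 0.24 and the vasopressin gene AVP at 1.39 ± 0.21. Genes lower on all 3 days, chosen by the same ranking, differed less. SELENOP, a selenium carrier, stood at -1.15 ± 0.27, the matrix protein gene ABI3BP at -0.98 ± 0.23, the thrombospondin gene THBS3 at -0.79 ± 0.14, EFCAB2 at -0.74 ± 0.13 and B4GALT3 at -0.80 ± 0.14. IVD and SIRT5 lay at -0.70 and -0.62. Under normexp these were closer to 0, with ABI3BP at -0.56, THBS3 at -0.47, B4GALT3 at -0.36 and IVD at -0.30. HESX1 and GTF3C2 were also chosen by this ranking, but the sign of both on day 3 turned when all their probes were averaged.

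None of these genes passed the test. limma called 0 of 20089 features for the HPD effect (smallest adjusted p = 0.555), with 1722 at an unadjusted p under 0.05, 1440 higher and 282 lower. This balance may partly come from the scaling and was not counted under other scalings. There the median HPD effect of all features was 0.02 (quantile normalization), 0.02 (median shift) and -0.0011 (normexp) in place of 0.09. The count of called features was 0 under every alternative too, where the smallest adjusted p ran from 0.102 (LPL, with normexp) to 0.870 (no day block) and unadjusted counts from 899 to 1834. Of 18027 features well above background on all arrays, 17 were at least 2-fold higher on all 3 days and 0 at least 2-fold lower on all 3. The named ones among the 17 were AVP, CXCL5, EGLN3, KMO, LGALS3, LGALS4, LPL and MMP12. A further 30 features were 2-fold lower on day 3 and 2-fold higher on days 5 and 7, among them the neutrophil calprotectin genes S100A8 and S100A9 and, named after its values were seen, HSD11B1. Across 20089 features, which are not independent replicates, the HPD difference correlated between days at r = 0.0353 (days 3 and 5), 0.0834 (days 3 and 7) and 0.0758 (days 5 and 7), and 54.6%, 60.5% and 59.7% of features had the same sign. With normexp the correlation of days 3 and 5 was -0.0833.

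By gene list, inflammatory cytokines and chemokines rose with HPD as a set: 18 of 23 measured members were higher, 14 of them on all 3 days, with a median of 0.35 and a mean of 0.58 (camera adjusted p = 0.00215). That call was lost at adjusted p = 0.972 with an estimated correlation and at 0.917 by fry, and the adjusted p ran from 9.54e-07 to 0.972 over its 14 alternatives. No member was called over all genes, and 8 were when adjusted over the list alone. The largest was CXCL8, a neutrophil attractant, at 1.96 ± 0.46 (1.78-fold, 8.74-fold and 3.78-fold on days 3, 5 and 7). The macrophage chemokine gene CCL4 stood at 1.42 ± 0.38, IL1B at 0.96 ± 0.32 and TNF at 0.89 ± 0.13, while IL1RN, listed here as well, encodes a blocker of interleukin-1. Macrophage markers were not called (camera adjusted p = 0.0709, and 0.972 with an estimated correlation). Their median was 0.40 with 12 of 14 higher, but on day 3 it was 0.14, within its random range. Among them the scavenger receptor genes MSR1 and CD36 stood at 1.02 ± 0.26 and 0.72 ± 0.15 and the endotoxin receptor gene CD14 at 0.79 ± 0.18. Neutrophil markers had a median of 0.28 (adjusted p = 0.613). On the slide of day 3 the cytokine median was 0.31 and in a fit of the other slide 0.38 (adjusted p = 4.71e-04).

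Cell cycle genes fell with HPD as a set, with 20 of 23 members lower and 7 of them on all 3 days, at a median of -0.19 (camera adjusted p = 5.99e-05). The call was lost at adjusted p = 0.972 with an estimated correlation and at 0.917 by fry (range over 14 alternatives 1.93e-07 to 0.972), and 0 members were called over all genes or when adjusted over the list alone. The mitotic kinase genes CDK1, AURKA and AURKB stood at -0.50 ± 0.15, -0.41 ± 0.15 and -0.34 ± 0.17, and the cyclin gene CCNE1 at -0.43 ± 0.21. The median was -0.38 on the slide of day 3, where red cell and neutrophil markers were lower as well, and -0.05 in a fit of the other slide (0.03 on day 5, -0.19 on day 7), so that without day 3 the adjusted p was 0.126. Without day 5 the cytokine call ended (adjusted p = 0.0706), as it did without the day block (adjusted p = 0.135). Leaving out days also called other lists, giving 5 without day 3, 4 without day 5 and 6 without day 7 in place of 2. Without day 3, neutrophil (adjusted p = 4.78e-06), lymphocyte (0.00111) and macrophage (0.00768) lists were called higher and granulation tissue matrix lower (0.00363). Bone matrix was called higher without day 5 (adjusted p = 0.0445) and lower without day 7 (0.0422).

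The remaining lists were not called for the HPD effect. Hypoxia and glycolysis had a median of 0.39 (adjusted p = 0.137), lymphocyte 0.28 (0.212), erythroid and blood -0.34 (0.137), granulation tissue matrix -0.13 (0.142), matrix proteases and inhibitors 0.18 (0.451, 1 member when adjusted over the list alone), skeletal muscle 0.02 (0.452), unfolded protein response -0.03 (0.451) and cartilage -0.03 (0.451). Osteoclast stood at 0.09 and angiogenic factors at 0.21 (0.774 each), Wnt signalling at 0.13 (0.899), endothelial at 0.11 (0.916), osteoblast and bone matrix at 0.02 (0.916), TGF-beta and BMP signalling at 0.07 (0.877), mast cell at 0.12 (0.916), interferon response at -0.05 (0.833), brain and meninges at 0.07 (0.941), adipocyte at -0.18 (0.916), epidermis at 0.09 (0.916), tooth formation at 0.08 (0.843) and reference genes at 0.13 (0.898). Median, mean and test direction differed in sign for 11 of these, namely bone matrix, TGF-beta, mast cell, interferon, unfolded protein response, skeletal muscle, brain, adipocyte, epidermis, tooth formation and reference genes. The median of reference genes, the control list, lay above its random range for the HPD effect (percentile 99.7), though within it on each single day. How far this bears on the random ranges of other lists was not tested. Macrophage and hypoxia lists were called with quantile normalization (adjusted p = 0.00969 each) and, with matrix proteases, under normexp. Under normexp the medians were smaller, at 0.21 for cytokines, 0.18 for hypoxia and 0.08 for lymphocyte genes. The median of all features was 0.09 for the HPD effect and 0.14, 0.09 and 0.06 on days 3, 5 and 7, and under normexp it was -0.10 on day 5.

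**Figure D1:**
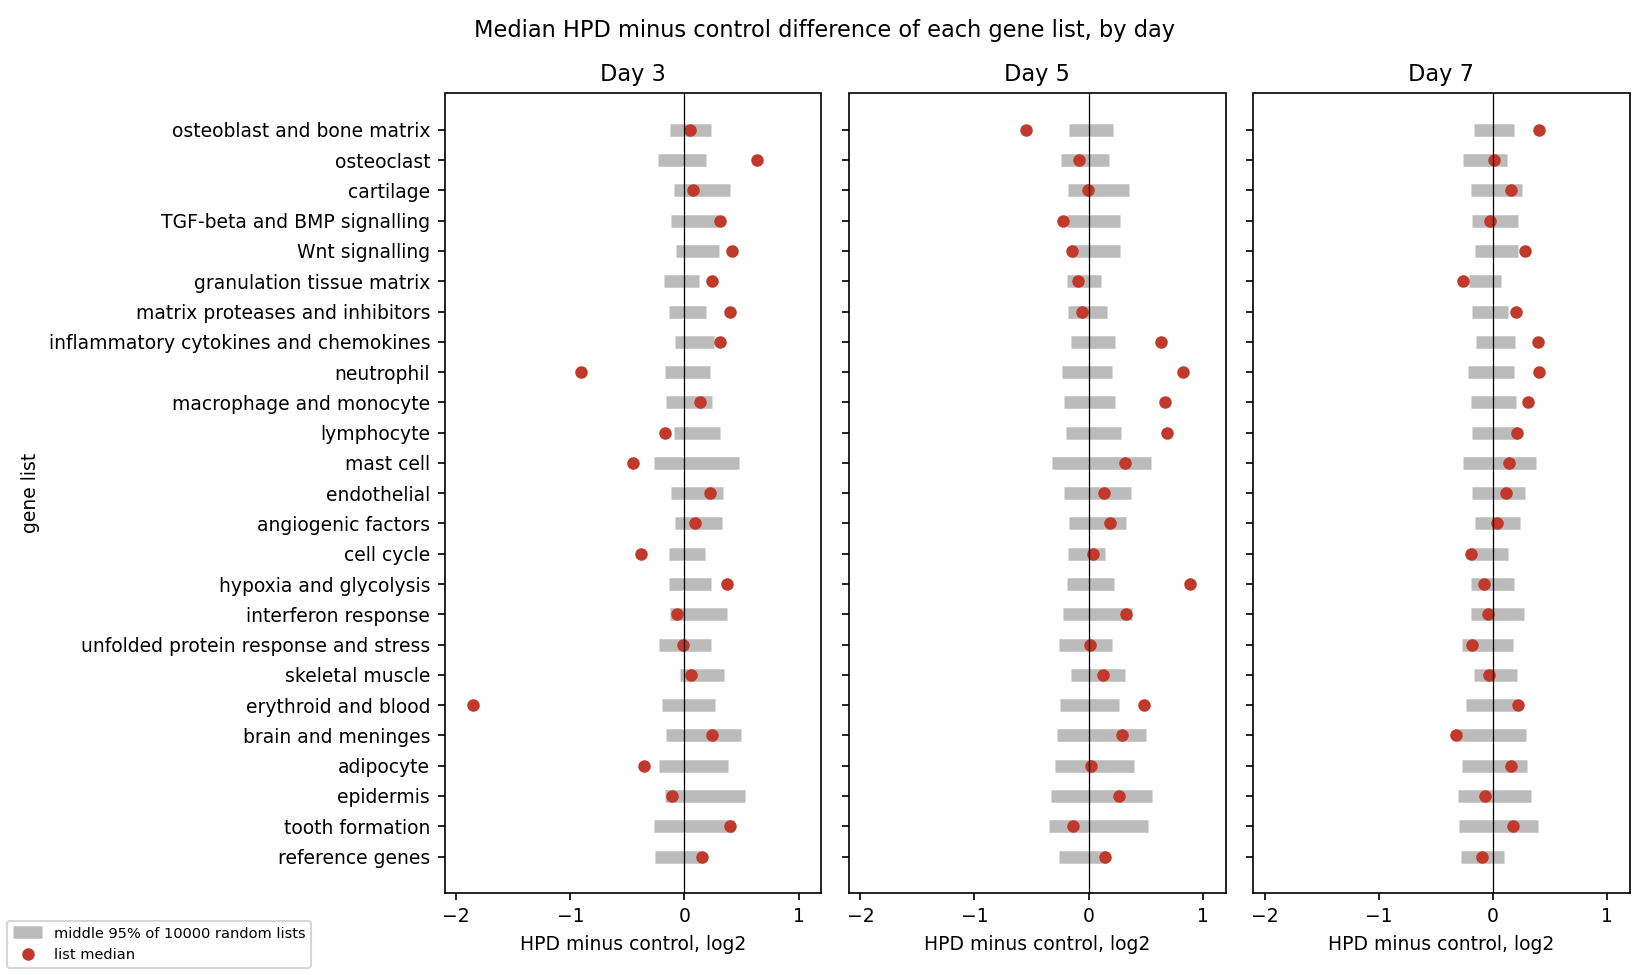
Median HPD minus control difference (x axis, log2) of each of the 25 gene lists (y axis) on days 3, 5 and 7, as red dots, with grey bars for the middle range of 10000 matched random lists. Bone matrix lies at -0.55 on day 5 and 0.41 on day 7, and red cell markers at -1.85 on day 3.

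On day 3, osteoclast genes were higher in filled than in empty defects, at a median of 0.64 (percentile 100 among random lists). The proton pump gene ATP6V0D2 was 3.34-fold higher, the fusion receptor gene DCSTAMP 2.37-fold, the bone collagen protease gene CTSK 2.33-fold and ACP5, the tartrate-resistant phosphatase, 2.14-fold. Wnt signalling (0.41), matrix proteases (0.40, with MMP12 4.75-fold and MMP14 2.75-fold higher), hypoxia (0.37), cytokines (0.31), TGF-beta (0.31) and granulation tissue matrix (0.24) also lay above their random ranges. Red cell genes lay far below, at -1.85 (percentile 0), with the Rh glycoprotein gene RHAG at -2.69 and the heme synthesis gene ALAS2 at -1.75. Neutrophil markers stood at -0.91 (percentile 0), with the myeloperoxidase gene MPO at -2.74, LCN2 at -2.36 and CAMP at -1.92, and cell cycle genes at -0.38 (percentile 0). Mast cell (-0.45), adipocyte (-0.35) and lymphocyte genes (-0.17) also lay below their random ranges.

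The eosinophil granule genes PRG3 and EPX had the lowest differences on day 3, at -3.53 and -3.43, followed by SLC35F4 at -3.42, the tropomodulin gene TMOD1 at -2.97 and the myeloid gene MS4A3 at -2.95. The highest were the taurine transporter gene SLC6A6 (13.0-fold), GAS7 (11.5-fold), the aminopeptidase gene ANPEP (10.9-fold), FRAS1 (9.50-fold) and C7H1orf146 (9.46-fold), though probes of FRAS1 and C7H1orf146 differed in the sign of their mean over days (-0.27 to 0.59 and -0.09 to 1.13). The sources used here do not say whether blood, which the series' design text mentions, entered any of these samples, and so what the day 3 differences in red cell, neutrophil and eosinophil genes stand for is open. SLC35F4 was well above background on the day 3 arrays alone. At least 2-fold apart were 1296 of 19735 features, 709 higher and 587 lower (named genes 209 and 207). Quantile normalization turned this to 472 higher and 729 lower and normexp to 208 and 338, and quantile normalization moved the median of all features from 0.14 to 0.04. Under normexp SLC6A6 stood at 1.82 and GAS7 at 1.94 in log2, and the Wnt median at 0.22. Counted as bounds, 214 more were higher and 48 lower.

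On day 5, hypoxia and glycolysis genes were higher with HPD at a median of 0.89 (percentile 100), with EGLN3 14.2-fold, the glucose transporter gene SLC2A3 2.95-fold, the vasodilator gene ADM 2.78-fold and the hexokinase gene HK2 2.19-fold higher. Leukocyte lists were higher too: neutrophil at 0.83 (S100A8 3.23-fold, S100A9 2.80-fold), lymphocyte at 0.69 (the T cell receptor chains CD3G 2.60-fold and CD3E 2.41-fold), macrophage at 0.67 (MSR1 2.89-fold, CHIT1 2.74-fold, CD14 2.23-fold) and cytokines at 0.64 (CXCL8 8.74-fold, CCL4 5.10-fold), each at percentile 100, and red cell genes at 0.48. Bone matrix genes were lower, at a median of -0.55 (percentile 0). DMP1, an osteocyte matrix protein, stood at -2.27, the keratan sulfate proteoglycan gene OMD at -2.18, the bone sialoprotein gene IBSP at -2.09, the phosphate regulator gene PHEX at -1.83 and the collagen gene COL1A1 at -1.26, while the osteoblast regulators RUNX2 and SP7 stood at -0.70 and 0.01. TGF-beta and BMP signalling was at -0.23 (percentile 1.05). Under normexp the day 5 medians were 0.47 for hypoxia, 0.19 for lymphocyte, 0.28 for cytokine and 0.24 for red cell genes, with CD3E at 0.07, SLC2A3 at 0.39, ADM at 0.38 and HK2 at 0.13 in log2, while bone matrix stayed at -0.49. Negative control spots varied more on the HPD than on the control array of day 5 (standard deviation 14.8 against 2.88) and day 7 (8.32 against 2.74), unlike day 3 (8.29 against 10.1). The lowest signal well above background was also higher with HPD (-4.98 against -5.53 on day 5, -4.57 against -5.34 on day 7). How far this raised dim genes on the HPD arrays was not tested.

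The highest single genes on day 5 were the carbonic anhydrase gene CA4 (15.6-fold), EGLN3, NEK10 (13.1-fold), the cytokine gene IL19 (9.04-fold) and CMTM2 (8.80-fold), and the lowest were MINAR1 at -4.58, the ubiquitin hydrolase gene UCHL1 at -3.38, TADA1 at -3.07, RBM28 at -2.82 and CNGA4 at -2.61. Under normexp CA4 stood at 2.01, NEK10 at 1.33, IL19 at 0.74 and MINAR1 at -2.76 in log2. Probes of MINAR1 and NEK10 differed in the sign of their mean over days (-1.37 to 1.28 and -0.16 to 1.58). At least 2-fold apart were 1251 of 19093 features, 931 higher and 320 lower (named genes 342 and 153), with bounds for 163 more higher and 71 lower, and under normexp 365.

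On day 7, bone matrix genes were higher with HPD, at a median of 0.41 (percentile 100). COL1A1 was 2.22-fold, DMP1 2.01-fold, IBSP 1.94-fold, PHEX 1.85-fold and OMD 1.68-fold higher. Neutrophil markers (0.40, with the iron-binding lipocalin gene LCN2 6.19-fold and S100A8 3.73-fold higher) and cytokines (0.40, with PTGS2 3.87-fold and CXCL8 3.78-fold) were also at percentile 100, followed by macrophage (0.30), Wnt signalling (0.29), red cell (0.23) and matrix protease genes (0.20). Granulation tissue matrix lay at -0.26 (percentile 0.15), with the smooth muscle actin gene ACTA2 at -1.28 and the periostin gene POSTN at -1.20, with brain markers at -0.32 (percentile 1.99) and cell cycle genes at -0.19 (percentile 2.05) below their ranges too. Under normexp the medians were 0.33 for bone matrix, 0.23 for neutrophil, 0.22 for cytokine, 0.13 for Wnt and 0.09 for protease genes and -0.04 for brain markers. With the mean of a gene's probes the protease median was 0.01, the red cell median 0.10 and that of granulation tissue -0.16.

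The highest genes on day 7 were HOXC6 (14.8-fold), the secretoglobin gene SCGB1D (10.3-fold), RABIF (9.73-fold), the serotonin receptor gene HTR5A (7.84-fold) and SLC35D3 (6.89-fold), and the lowest N4BP2L1 at -3.78, the uracil glycosylase gene UNG at -3.16, GP5 at -3.06, the dermatopontin gene DPT at -2.86 and CNTN1 at -2.56. GP5 was well above background on the day 7 arrays alone. Other probes of HOXC6, SCGB1D and HTR5A gave means over days down to 0.22, 0.11 and -0.21, under normexp HOXC6 stood at 1.62 and SCGB1D at 1.80 in log2 on day 7, and normexp turned the day 5 sign of SCGB1D, HTR5A and C7H1orf146. At least 2-fold apart were 461 of 18462 features, 302 higher and 159 lower (named genes 110 and 83), under normexp 120. Without the filter on dim features the balance was 569 higher and 762 lower, and bounds added 67 higher and 81 lower.

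**Figure D2:**
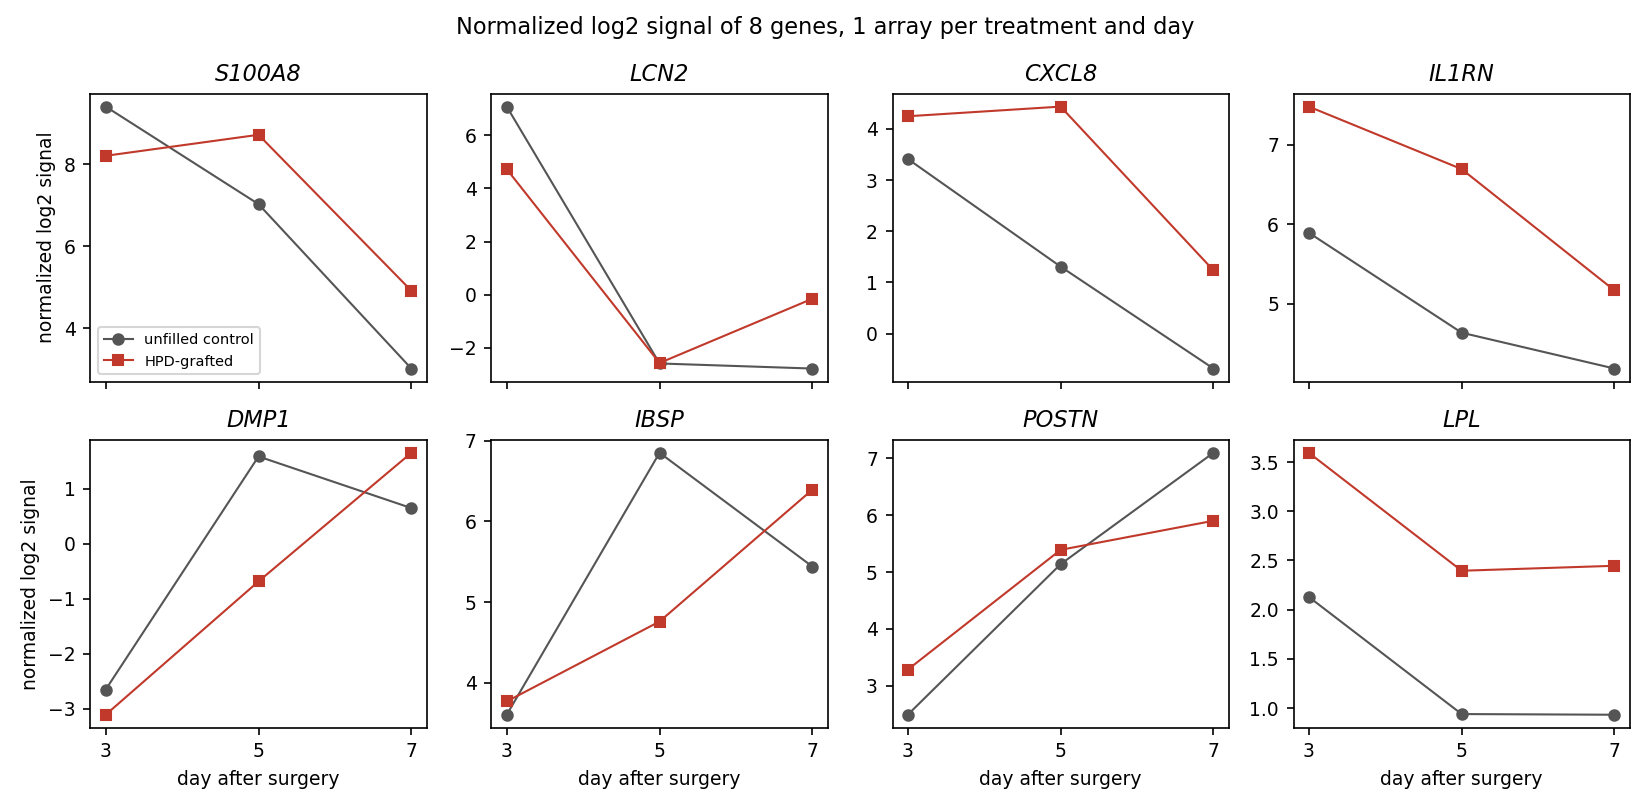
Log2 signal relative to the array's 75th percentile (y axis) of 8 genes by day after surgery (x axis), with control as grey circles and HPD as red squares, 1 array each. LCN2 differed by -2.36 on day 3 and 2.63 on day 7, and IBSP by -2.09 on day 5 and 0.95 on day 7.

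Time was compared over both treatments to describe how the tissue changed from day 3 to day 7. OGN, which encodes the proteoglycan osteoglycin, was 4.49 ± 0.35 (SE, 6 arrays) above its day 3 level on day 7, DMP1 4.03 ± 0.79, the growth factor gene PTN 3.94 ± 0.27, ITGBL1 3.75 ± 0.32, the fibrillar collagen gene COL11A2 3.67 ± 0.60, POSTN 3.62 ± 0.51, the tendon gene TNMD 3.40 ± 0.57 and OMD 3.16 ± 0.71, followed by LIX1 and ITM2A. The lowest were antimicrobial genes of granulocytes: LCN2 at -7.37 ± 1.19, the cathelicidin gene CAMP at -7.45 in control and -4.54 in HPD arrays, and MCP-1, here a defensin (macrophage cationic peptide), at -5.26 ± 0.50. PRG3, EPX, S100A8 and S100A9 lay between -5.41 and -4.81, and SERPINB10, ARG1 and the chemokine gene CCL5 between -3.98 and -3.86. All had the same sign in control and HPD arrays, as with LCN2 at -9.87 in control and -4.88 in HPD arrays. From day 5 to day 7, on a shared slide, OGN differed by 1.47, POSTN by 1.24 and DMP1 by 0.70, whereas LCN2 and CAMP stood at 1.11 and 1.45.

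Of these genes none passed limma in the main setting (adjusted p from 0.119), and all but PRG3 (0.0513) and EPX (0.0566) did under normexp (OGN 0.00483, LCN2 0.0156), where TNMD stood at 1.88, PRG3 at -3.67 and EPX at -3.12. limma called 1 of 20089 features between days 7 and 3, with 4176 at an unadjusted p under 0.05 (2158 higher, 2018 lower), 1 between days 5 and 3 (3273 unadjusted) and 0 between days 7 and 5 (1626 unadjusted, with 2 under normexp and 1 with the trend and robust prior). The called feature, ENSOCUT00000010166, which has no symbol here, rose by 5.01 ± 0.16 from day 3 to day 7 (adjusted p = 0.0443) and by 5.07 to day 5 (adjusted p = 0.0420). It stood at -4.11 and -4.37 on day 3 and between 0.65 and 1.02 on later days. The count between days 7 and 3 was 0 with quantile normalization, without the dim filter or without day 5, and 911 under normexp (496 higher, 415 lower), where the median of all features was 0.17 in place of -0.01. All day 3 arrays lay on another slide than the later ones.

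Granulation tissue matrix rose as a set from day 3 to day 7, with 19 of 22 members higher at a median of 1.08 (camera adjusted p = 9.25e-06; adjusted p = 0.654 with an estimated correlation). No member was called over all genes (11 under normexp) and 12 when adjusted over the list alone; besides POSTN they were led by ACTA2 at 2.33 ± 0.49, the keratan sulfate proteoglycan gene LUM at 2.31 ± 0.33 and COL5A2 at 2.22 ± 0.47. Bone matrix genes rose at a median of 0.56 (adjusted p = 0.00984; adjusted p = 0.654 with an estimated correlation), osteoclast genes at 0.57 (0.00655; 0.654 estimated) and cartilage genes at 0.19 (0.0434; 0.654 estimated), with 0, 0 and 1 members when adjusted over the list alone and 0 over all genes (3, 1 and 1 under normexp). PHEX stood at 2.65 ± 0.67, IBSP at 2.23 ± 0.76, ACP5 at 2.37 ± 0.46, MMP9 at 0.98 ± 0.35 and COL10A1, a collagen of mineralizing cartilage, at 1.30 ± 0.31 (0.70 under normexp). The bone matrix call ended under normexp (adjusted p = 0.0693), and the cartilage call without the dim filter (0.0573) and with the trend and robust prior (0.0777). Within the slide of days 5 and 7 the medians were 0.63 for granulation tissue, 0.33 for bone matrix, 0.15 for osteoclast and 0.22 for cartilage. For bone matrix this was -0.22 between the control arrays and 0.87 between the HPD arrays.

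Neutrophil genes fell as a set from day 3 to day 7, with 15 of 15 lower at a median of -2.84 (camera adjusted p = 2.70e-07; adjusted p = 0.654 with an estimated correlation). The neutrophil median was -3.40 between the control arrays and -1.83 between the HPD arrays, where red cell genes stood at -0.89 and 0.66. Cell cycle genes fell at -0.66, with 22 of 23 lower (1.34e-07; 0.654 estimated), led by AURKA at -1.44 ± 0.19 and AURKB at -1.36 ± 0.21, and cytokines at -0.79, with 19 of 23 lower (3.86e-05; 0.654 estimated), including IL6 at -3.57 ± 0.39, CXCL8 at -3.55 ± 0.56 and IL1B at -2.49 ± 0.39. Macrophage genes fell at -0.53 (8.42e-04; 0.654 estimated), with the scavenger receptor gene MARCO at -3.62 ± 0.32, lymphocyte genes at -0.42 (9.89e-04; 0.654 estimated), with LCK at -1.94 ± 0.42 (-0.60 under normexp), and adipocyte genes at -1.17 (0.00103; 0.654 estimated), with the fatty acid carrier gene FABP4 at -2.47 ± 0.26 and its regulator PPARG at -1.78 ± 0.18 (-0.95 under normexp). The list medians were -0.19 for lymphocyte and -0.38 for cytokine genes under normexp, and -0.78 and -1.26 with the mean of a gene's probes. When adjusted over the list alone, 9 neutrophil, 13 cell cycle, 15 cytokine, 2 macrophage, 4 lymphocyte and 5 adipocyte members passed, against 0 over all genes in the main setting and 5, 8, 11, 3, 0 and 4 over all genes under normexp. Of the 11 cytokine members under normexp, 9 were lower and 2 higher. Within the slide of days 5 and 7 the medians were -0.39 for neutrophil, -0.40 for cell cycle, -0.33 for cytokines, 0.04 for macrophage, -0.04 for lymphocyte and 0.07 for adipocyte genes. By fry no list passed (adjusted p from 0.218). Median, mean and test differed in sign for endothelial, erythroid and tooth formation lists, none of which was called. Also not called, the control list of reference genes stood at -0.30 and hypoxia at -0.52, both below their random ranges. TGF-beta and BMP signalling stood at 0.30, above its range. Under normexp the reference gene, hypoxia, mast cell and unfolded protein response lists were called. How far the fall of reference genes bears on the other falling lists was not tested.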

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

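The limits that selected the results in this part, and all tests on the day 5 arrays, were chosen after the values had been seen. Each result below is an HPD difference with opposite signs on separate days; none of the differences between days was tested, since each day held 1 array per treatment.

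Among lists, the HPD minus control median of bone matrix was 0.96 higher on day 7 than on day 5 (0.41 against -0.55). TGF-beta and BMP signalling was 0.54 higher on day 3 than on day 5, and granulation tissue matrix 0.50 higher on day 3 than on day 7. Day 5 exceeded day 3 by 1.74 for neutrophil, 0.85 for lymphocyte and 2.33 for erythroid and blood genes.

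Among granulocyte genes, the day 7 difference exceeded that of day 3 by 4.67 for PRG3, 4.46 for EPX, 4.99 for LCN2 and 3.10 for S100A8, and the day 5 difference exceeded it by 3.01 for S100A9 and 3.75 for SERPINB10. The same holds of the red cell gene HEMGN by 3.34 and the interferon-induced gene IFIT3 by 2.23 (day 5 over day 3). For the endothelial receptor gene TEK the day 3 difference exceeded that of day 5 by 3.75. For DPT and CNTN1 the day 5 difference exceeded that of day 7 by 4.22 and 3.62. For DMP1 and COL1A1 day 7 exceeded day 5 by 3.27 and 2.41.

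The pattern weighed here is the low bone matrix list with HPD on day 5, at -0.55 between 0.05 on day 3 and 0.41 on day 7. A swap of the day 5 arrays is not settled: of 161 features at least 1.5-fold apart one way on days 3 and 7 and at least 1.5-fold apart on day 5, 142 (88.2%) went the same way on day 5, where 67.9% would follow from the larger share of higher features alone, but of the 15 that were lower on days 3 and 7 only 8 were lower on day 5. An earlier stage of healing in the day 5 HPD sample may contribute, since across 20089 features, which are not replicates, its difference from control correlated at r = -0.313 (-0.434 under normexp) with the change of the control arrays from day 3 to day 7, against 0.241 for the day 3 difference and the control change from day 5 to day 7, and -0.0430 for the day 7 difference and that from day 3 to day 5. Of the 14 lists beyond their random range in that control change, 8 lay beyond it the other way on day 5 and 0 the same way, but 6 lay within it, among them granulation tissue matrix (1.35 in control, -0.09 on day 5), cell cycle (-0.89 and 0.03), adipocyte (-1.26 and 0.02) and osteoclast (0.83 and -0.08), so this explanation is open too. Whether the graft delays bone formation, or that sample held less bone, was not tested.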

How the results depend on the processing

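The slide block in place of day and the left-out days for day comparisons were chosen after seeing the data. HPD calls stayed at 0 genes under every setting, and 2 lists were called with slide as the block. A slide term beside day could not be estimated and was not run; slide 1 holds day 3 alone. Scan dates were not used. No further paired analysis was possible because day is already the block that matches control with HPD. That both arrays of a day came from the same animals is assumed. Genes called between days 7 and 3 (1) became 0 with quantile normalization, 0 without a dim filter, 911 under normexp, 5 with features above background on all 6 arrays, 8 with the trend and robust prior and 0 without day 5. Between days 5 and 3 (1) the counts were 0 with quantile normalization, 0 without a dim filter, 126 under normexp, 2 with the trend and 0 without day 7. Between days 7 and 5 (0) they were 2 under normexp and 1 with the trend. Counts of features apart on day 3 (1296) were 546 under normexp, 3754 at 1.5-fold, 372 at 3-fold and 2306 without a filter. On day 5 (1251) they were 365, 3951, 326 and 2143 in that order, and on day 7 (461) 120, 1868, 120 and 1331. Looser and stricter folds move these by construction; for the rest the cause was not tested. Mean agreement between days, 0.0648, was 0.0966 over features above background on all arrays. HPD lists called (2) were 4 with quantile normalization, 5 under normexp, 0 with an estimated correlation, 0 by fry, 1 without the day block and 4 to 6 when leaving out each day. Lists called between days 7 and 3 (10) were 0 with an estimated correlation and 0 by fry, and 9 to 13 otherwise. With an estimated correlation, 2 residual degrees of freedom left camera hardly able to call any list. Of the adjusted p-values of the called lists under each alternative, 98 kept their side of the threshold and 30 lost it, with 0 reversed. Of the summary counts under each alternative, 51 stayed within their limits and 36, given above, did not. Between 78.1% and 86.4% of spots per array were well above background. For the rest, single-day folds of genes are only bounded. The fit, the list tests and the list medians used the dim values of tested features as they stood.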

Other observations

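The tests of slide and brightness and the splits of the samples were planned; those of neutrophils and macrophages, and the slide test under other scalings, were chosen after the result was seen.

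Between days 5 and 7, on the same slide, camera called 7 lists, of which granulation tissue matrix, cytokines, neutrophil and cell cycle were also called from day 3 to day 7. Hypoxia and glycolysis fell at a median of -0.35 (adjusted p = 0.00434), interferon response at -0.36 (0.0123) and reference genes at -0.18 (0.0467), and all 7 were lost at adjusted p = 0.774 with an estimated correlation. In that setting 2 residual degrees of freedom left camera hardly able to call any list. Reference genes had been included as the control list, so their call limits what the other calls at the preset correlation can show. The hypoxia median was 0.02 between the control arrays and -0.85 between the HPD arrays, and red cell genes stood at -0.26 and -0.84. Skeletal muscle genes had a median of 0.32 (14 of 20 higher, adjusted p = 0.0740).

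Slide and day are confounded for the lists called between days 7 and 3. Within the later slide, 5 of the 10 lists had a day 7 minus day 5 median beyond their random range in the called direction. These were granulation tissue matrix, bone matrix, cytokines, neutrophil and cell cycle. The count lay exactly at the limit set beforehand against a slide difference as the whole cause. It was 5 with quantile normalization and 5 under normexp, where bone matrix shrank from 0.33 to 0.19 and cytokines from -0.33 to -0.17. With the mean of a gene's probes it was 8. Camera called 4 of the 5, bone matrix excepted, and these 4 lay beyond range in control and in HPD arrays. For these 4 the medians argue against slide as the whole cause, but only weakly. The random lists draw genes independently, whereas the estimated correlations of the 5 lists were 0.20 to 0.57. Bone matrix passed through the HPD arrays alone, at 0.87 against -0.22 between the control arrays. Osteoclast genes lay within range in that fit, at 0.15, but beyond it in the control and in the HPD arrays taken separately (0.17 and 0.33), so a slide difference as the whole cause is not settled for them. For macrophage, adipocyte, cartilage and lymphocyte lists slide and day cannot be told apart, the last pair lying beyond range in the HPD arrays alone (0.37 and -0.31) or with the mean of a gene's probes. Whether array brightness acted through the scaling cannot be decided by these list tests. They compare a list with the other genes, and a constant shift per array moves both alike. All 10 lists kept call and direction with quantile normalization. Under normexp 9 did, and the bone matrix call ended (camera adjusted p = 0.0693).

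For the cytokine list, higher with HPD on all 3 days, the day 3 neutrophil median of -0.91 gives no sign of more neutrophils in the filled defect. It comes from an array pair whose red cell median was -1.85. What these day 3 differences stand for is open, so that median cannot decide for or against more neutrophils. On days 5 and 7 the neutrophil median lay above its random range on both of the 2 days (0.83 and 0.40), so more neutrophils may contribute there. More macrophages may contribute as well: their median lay above its random range on 2 of 3 days (0.14, 0.67 and 0.30 on days 3, 5 and 7), which leaves that explanation open. An effect of the graft on cytokine expression within cells was not tested.

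The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, 10 of the 10 splits, the real one included, called as many as the real 0, which any split must, and the highest of the others was 0. For lists, 10 of 10, the real one included, called at least the real 2, and the highest of the others was 12. With day as the block, 6 of the 10 splits rest on the array pair of a single day and give the same result in pairs, so only 3 other splits regroup the samples. These called 12, 9 and 4 lists and equal the HPD difference with the sign of day 5, day 3 or day 7 reversed. Their calls, up to several times the real count, cannot be assigned to a cause. List differences between HPD and control varied by day (bone matrix at 0.05, -0.55 and 0.41, neutrophil at -0.91, 0.83 and 0.40 on days 3, 5 and 7). With 1 array per treatment and day, this cannot be told from variation between single arrays. The preset correlation also lay below the estimates for the 2 called lists (0.24 for cytokines, 0.48 for cell cycle). All splits reuse the same 3 HPD minus control differences, so none shows a count of lists free of an HPD effect. The count of lists alone does not single out the HPD grouping, and the splits cannot decide for or against it.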
